A study of Rattus norvegicus with 10 samples.

How the data were processed

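Total RNA of the rat hepatic stellate cell line HSC-2 was labelled with biotin by a one-cycle protocol for Affymetrix arrays, per the labels' protocols. The 10 arrays were an untransfected line, a line with a scrambled control sequence and 3 clones overexpressing miR-146a, each at passages 42 and 43. The series text names the untransfected and the scrambled line as controls. Nothing in the labels says that the passages came from separate cultures or transfections, so p-values between single lines measure only the spread between these samples, which may be technical.

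The deposited values are intensities on a linear scale, 1 column per array, from 20 to 30192, made with RMA per the submitters' processing notes. The version, and whether the table was returned from the log2 scale, are not given in the sources used here. A log2 table had been assumed when the tests were fixed, so log2 of the deposited intensities was taken before each test. Of the deposited intensity values, 14.6% were exactly 20 and none was lower. This floor has no order below it, so a gene at the floor on all arrays of one side has only a lower bound of its fold change, taken against the floor. Medians per array lay between 97.2 and 103.4 intensity units, and the number of arrays limits the precision.

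Of 31099 probe sets, 57 array controls and 3522 at the floor on all arrays were left out, and 27520 were tested. Gene names came from the platform annotation, in which 19202 tested probe sets had 1 symbol (13286 genes), 399 several and 7919 none. Matching by gene identifier to the gene table of the rat assembly GRCr8 found 19142 of these probe sets and changed 0 symbols. That table was used only for names and for the order of neighbouring genes, and no coordinates from it are given. Genes were named only from probe sets with 1 symbol. Where a gene had several, genes named by their change or range were taken from the one with the smallest p. Members of the gene lists, with Irak1, Traf6 and Smad4, were taken from the one with the highest mean.

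Tests used limma 3.58.1 in R 4.3.3 with eBayes and Benjamini-Hochberg adjusted p under 0.05. The clones were compared with the control lines on 5 line means, each over 2 passages, so that the line was the replicate (3 residual degrees of freedom). Single clones, the scrambled against the untransfected line, and differences between clones (an F test) were tested on 10 arrays with 1 coefficient per line (5 residual degrees of freedom). Passages were compared with line as a block. Calls shared by the clones were set beside 20 simulations of unchanged clones against the same controls, drawn with the spread between passages and no differences between lines. The change between passages was compared between clones and control lines after the data were seen. Neighbouring genes were examined with medians over 25 of 6622 genes in order, in 6117 windows, against 1000 permutations of the gene order.

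For each of 21 gene lists, camera with a preset inter-gene correlation of 0.01 was run on 1 probe set per gene, the one with the highest mean, with an estimated correlation and fry as alternatives. Lists covered reported miR-146a targets, inflammatory, interferon, contractile, matrix, matrix protease, TGF-beta and BMP, quiescent stellate cell, growth factor, cell cycle, cholesterol, p53, endoplasmic reticulum stress, hypoxia, immediate early and oxidative stress genes, and markers of 5 groups of other cell types. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, by log2 fold change among those past the threshold, 12 genes in each direction for the clones together (with all 6 clone arrays on one side of the 4 control arrays), 6 for each clone and for passage, 8 for the scrambled line, up to 8 by range between clones, up to 4 per list, and Irak1, Traf6 and Smad4. Genes at the ends of runs of neighbours, those whose passage change differed, and Alb as an abundant hepatocyte marker were chosen after their values were seen. A planned test of miR-146a seed sites was not run, because 3' untranslated regions were not used here.

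Whether the passage numbers pair the samples was checked by correlating the passage deviations of the lines over probe sets. All 10 pairs of lines correlated above 0.1, from 0.136 to 0.648, so the passage number was taken to pair the samples. Correlations were 0.541 to 0.648 among the clones and 0.136 between the control lines. The main tests of single clones, the scrambled line and differences between clones had no passage term. Their SE and p-values therefore do not use this pairing. Values with the passage number as a replicate block are given where they moved a count by over 1.5 times.

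The procedures were tested on simulated data with 200 of 27520 probe sets changed, drawn only from the brighter ones and without a floor. Differences between lines were simulated only for the clones together and for passage. The shares below thus do not cover dim probe sets, nor, in the other comparisons, differences between lines. For the clones against control lines, 67% of changes of 1 and 94% of changes of 2 on the log2 scale were recovered, with 8.52% of calls false. The shares recovered were 78% and 100% for clone S1, 71% and 96% for the scrambled line, 92% and 100% for passage, and 67% and 97% for differences between clones, with 4.81%, 5.65%, 11.1% and 4.65% of calls false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Alternatives covered a filter on dim probe sets, a trended robust prior, quantile normalisation, median centring, 1 probe set per gene, a 2-fold minimum, either control line alone, other error models, and leaving out each line, passage or array. With a single control line, the spread of the line means came from the clones alone and held no difference between control lines. Sizes of change are therefore given for those fits, without p-values.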

Results

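Gene expression was measured on Affymetrix arrays in 5 lines of HSC-2, a cell line of hepatic stellate cells from Wistar rats. Stellate cells are the retinoid-storing pericytes of the liver that become contractile, matrix-producing cells after injury. The lines were the untransfected cells, a line carrying a scrambled control sequence, and 3 clones, called S1, S4 and S5, that overexpress the microRNA miR-146a, a feedback inhibitor of signalling from Toll-like and interleukin-1 receptors. Each line was sampled at passage 42 and at passage 43, which gave 10 arrays. Of 31099 probe sets, 27520 were tested, and the array medians lay between 97.2 and 103.4 intensity units. Mature miR-146a was not analysed here, so its overexpression is taken from the labels.

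The first 2 principal components of the 10 arrays held 39.0% and 27.9% of the variance. On the first, the 6 clone arrays lay between 15.2 and 32.8 and the 4 control arrays between -48.7 and -22.1. On the second, the untransfected arrays were at 17.1 and 46.5 and the scrambled arrays at -46.5 and -38.2, while the clone arrays lay between -1.32 and 9.21. Across probe sets, arrays of different clones correlated at 0.987 to 0.997, clone and control arrays at 0.964 to 0.981, and scrambled and untransfected arrays at 0.960 to 0.977. Probe sets are not independent replicates of one another.

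**Figure D1:**
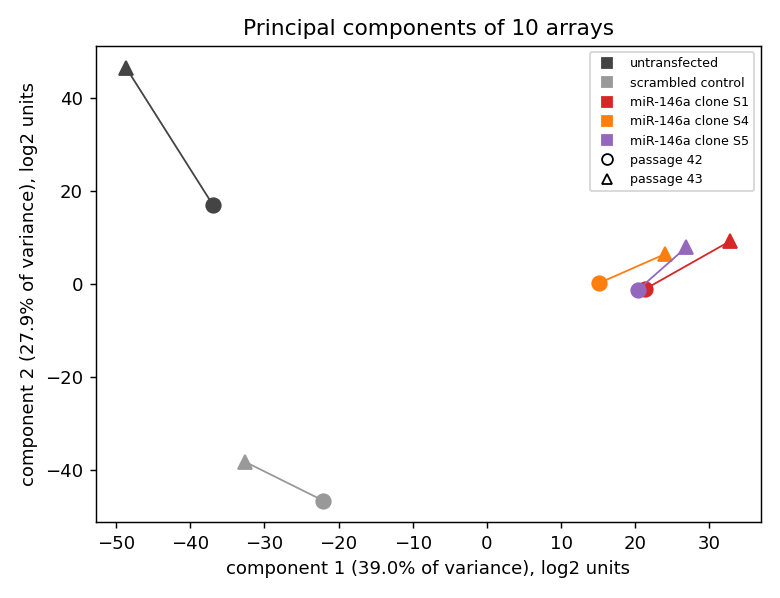
Each point is an array, placed by its first component (horizontal axis, 39.0% of variance) and second component (vertical axis, 27.9%), both in log2 units. Colours mark lines, circles passage 42, triangles passage 43, and a line joins the passages of one line. The 6 clone arrays lie together on the right, and the untransfected and scrambled arrays lie apart from them and from each other.

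The main comparison asked which transcripts differed between the miR-146a clones and the control lines. Plagl1, a zinc finger transcription factor encoded by an imprinted gene, was higher in the clones by 6.38 on the log2 scale (SE 0.15, 3 clones against 2 control lines, limma adjusted p = 0.00158). Its mean log2 level was 10.74 ± 0.23 (SD, n = 3) in the clones and 4.36 ± 0.0017 (SD, n = 2) in the control lines, where 2 of the 4 arrays were at the floor of the deposited values and the other 2 at 4.40 and 4.41, against a floor of 4.32. The control side was thus not above background, so each change given for Plagl1 is a lower bound and its SE and the control SD reflect the floor. Col15a1, a collagen of basement membrane zones, was lower in the clones, at -4.40 (SE 0.10, limma adjusted p = 0.00158). Mmp2, the gelatinase A that degrades basement membrane collagen, was at 8.50 ± 0.84 in the clones and 12.54 ± 0.09 in the control lines, a change of -4.05 (limma adjusted p = 0.0488).

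Eya1, a transcriptional coactivator with phosphatase activity, was higher by 4.19 (SE 0.27). Foxa2, a forkhead factor of endoderm and liver, rose by 2.87 (SE 0.27), and Thrb, the thyroid hormone receptor beta, by 2.78 (SE 0.21). Pappa2, a protease that cleaves insulin-like growth factor binding proteins, rose by 3.93 (SE 0.35), Pcsk6, a proprotein convertase, by 3.21 (SE 0.32), Sema3e, a secreted semaphorin, by 2.86 (SE 0.32) and Bmp4, a bone morphogenetic protein, by 2.72 (SE 0.22). Anxa3, a calcium-dependent phospholipid-binding protein, rose by 3.72 (SE 0.23), and Fgf13, an intracellular fibroblast growth factor homologue, by 3.64, a lower bound, from control arrays of which 3 of 4 were at the floor and 1 at 4.39. Fam13a rose by 3.98 (SE 0.40) and Cobll1 by 3.23 (SE 0.28).

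The genes with the largest falls included Pcp4, a regulator of calmodulin, at -4.83 (SE 0.44), Cdh13, a cadherin anchored by a lipid, at -3.54 (SE 0.25), and Olfm1, a secreted olfactomedin, at -3.44 (SE 0.13). The clone arrays of Olfm1 lay between 4.40 and 4.99, near the floor of 4.32, so its fall may be a lower bound and its SE may reflect the floor. Il1rl1, the receptor of interleukin-33, fell by 3.16 (SE 0.29). Star, which carries cholesterol into mitochondria, was at -3.13 (SE 0.23), Ptgs1, the constitutive cyclooxygenase, at -2.89 (SE 0.30), and Plin2, a coat protein of lipid droplets, at -2.12 (SE 0.23). Cryl1 was at -3.06 (SE 0.16), Pilrb2l4 at -2.72 (SE 0.11) and PCOLCE2, an enhancer of procollagen processing, at -2.19 (SE 0.23). All 24 of these genes passed the limma test, with all 6 clone arrays above or all below the 4 control arrays.

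**Figure D2:**
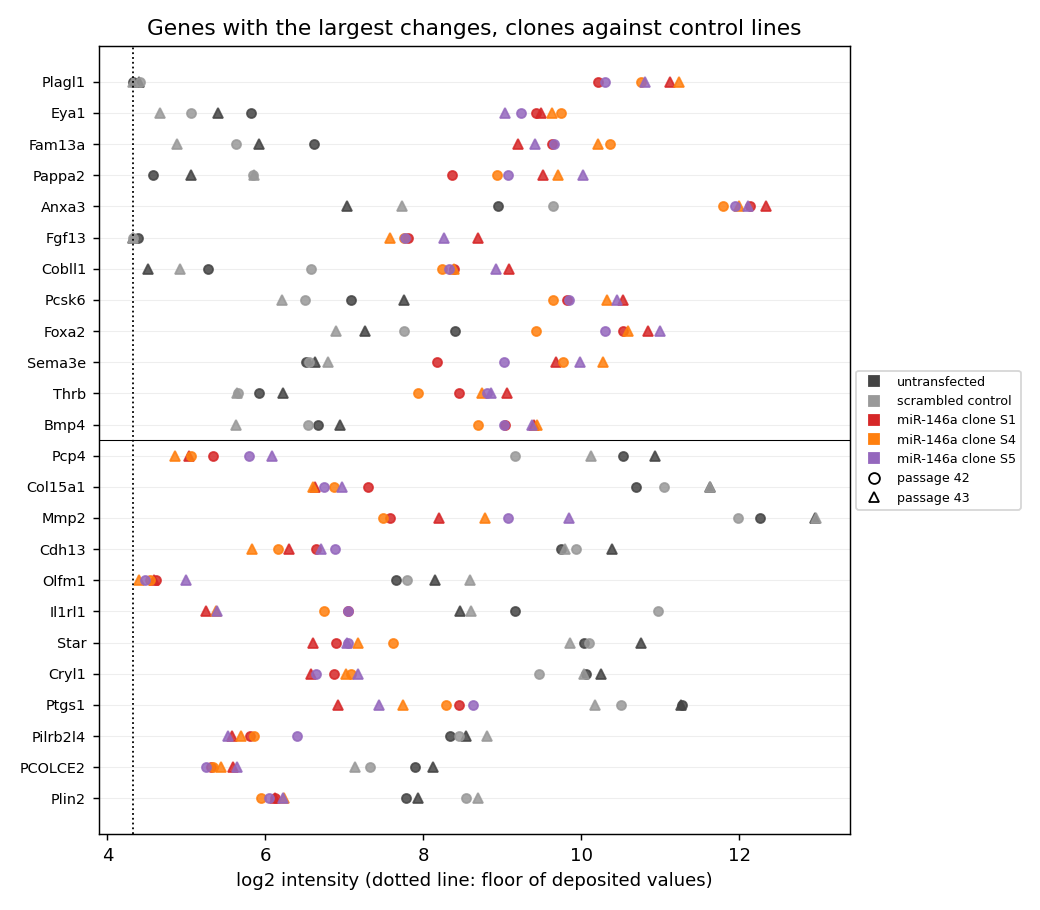
Log2 intensity (horizontal axis) of the 12 genes with the highest and the 12 with the lowest change past the threshold, 1 gene per row, each point an array, coloured by line and shaped by passage. The dotted line is the floor of the deposited values. In Plagl1 the clone arrays average 10.74 and the control lines 4.36, and in every row the clone and control arrays occupy separate ranges.

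In the fixed list of TGF-beta and BMP signalling, of which TGF-beta drives fibrogenic activation of stellate cells, 4 of 40 measured genes rose, none fell and 36 did not pass. Besides Bmp4 these were Id1 at 1.15 (SE 0.10), Id3 at 0.74 (SE 0.08) and Smad7 at 0.81 (SE 0.08). The Id genes are transcriptional targets of BMP signalling and Smad7 is an inhibitor of the pathway. Adjusted over the list alone, 5 rose and 2 fell. The list was higher than other genes by camera (adjusted p = 0.00689), with adjusted p = 0.861 with an estimated correlation. Fry, which asks whether a list's genes moved one way on balance and does not compare them with other genes, gave adjusted p = 0.205. With the untransfected line as the only control camera did not call the list, and with the scrambled line it did. The spread in both fits came from the clones alone.

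Among the 27 contractile and stellate activation genes, Cryab, a small heat shock protein, rose by 0.83 (SE 0.07) and Fap, a fibroblast surface protease, fell by 1.89 (SE 0.19). The other 25 did not pass. Thy1, a fibroblast surface glycoprotein, was at -4.26 (SE 0.68, limma adjusted p = 0.0785). Adjusted over the list alone, 1 rose and 2 fell. Of 51 collagen and matrix genes, Col15a1 alone passed, and 4 were lower and 0 higher adjusted over the list alone. Col6a2, a chain of the microfibrillar collagen VI, was at -2.23 (limma adjusted p = 0.0701) and Dcn, the proteoglycan decorin, at 2.45 (limma adjusted p = 0.248). Of 34 matrix proteases and inhibitors, Adam9, a membrane metalloprotease, rose by 0.70 (SE 0.07), Mmp2 fell and 32 did not pass. Adjusted over the list alone, 3 rose and 1 fell. Timp3, a metalloprotease inhibitor, was at 3.99 with an SE of 0.73 (limma adjusted p = 0.102).

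Of 37 inflammatory and NF-kB response genes, Ccl2, the monocyte chemoattractant, fell by 1.77 (SE 0.22, limma adjusted p = 0.0488) and 36 did not pass. Adjusted over the list alone, 2 fell. Ccl7, a related chemokine, was at -1.35 (limma adjusted p = 0.0990). The 34 interferon response genes had 0 past the threshold by limma, and camera gave adjusted p = 0.629. In the list of 32 oxidative stress and detoxification genes, Aldh1a3, a retinaldehyde dehydrogenase, rose by 1.31 (SE 0.15) and Gpx3, the secreted glutathione peroxidase, fell by 2.01 (SE 0.23). Adjusted over that list alone, 4 rose and 5 fell. Met, the receptor of hepatocyte growth factor, rose by 1.21 (SE 0.10) as 1 of 38 growth factor genes, with 2 higher and 4 lower adjusted over the list alone. Plin2 was 1 of 27 genes of quiescent stellate cells and retinoid handling to pass, with 1 higher and 1 lower adjusted over the list alone, and camera gave adjusted p = 0.656 for that list.

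Reported targets of miR-146a were examined as a group, because the clones carry more of this microRNA per the labels. None of the 23 measured targets passed, either over all probe sets or adjusted over the list alone. Irak1, a kinase of the interleukin-1 receptor pathway, was at -0.10 (SE 0.11, limma adjusted p = 0.726), Traf6, its downstream ubiquitin ligase, at -0.33 (SE 0.07, limma adjusted p = 0.149), and Smad4, the shared partner of the receptor-activated Smads, at -0.12 (SE 0.08, limma adjusted p = 0.525). The list's median was -0.04 and its camera adjusted p = 0.804. Its members went both ways, with 16 values below 0 and 7 above. Protein was not analysed here.

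The list of cholesterol synthesis and uptake had a median of 0.43 and a camera adjusted p = 0.00140, with 0 of 27 members past the limma threshold. With an estimated correlation its adjusted p = 0.861. Its median was -0.0060 against the scrambled line alone and 0.76 against the untransfected line alone. The list of endoplasmic reticulum and amino acid stress had a median of 0.11, 0 of 36 members past the threshold and a camera adjusted p = 0.0265, with adjusted p = 0.861 with an estimated correlation. It was not called against the untransfected line alone, and its camera adjusted p = 0.0800 without S1 and 0.0634 without S5. The lists of cell cycle (52 genes), p53 response (27), hypoxia and glycolysis (32) and immediate early response (29) had 0 members past the threshold, and their camera adjusted p were 0.2498, 0.245, 0.926 and 0.951. The medians of the contractile, matrix, growth factor, immediate early and portal fibroblast lists were 0.09, 0.06, -0.01, 0.06 and -0.03, their means -0.15, -0.0011, 0.05, 0.02 and 0.08, and camera placed the immediate early list lower and the others higher. The contractile list had a median of 0.36 against the scrambled line alone and -0.26 against the untransfected line alone, and the cell cycle list -0.44 and 0.26. The interferon, matrix and p53 lists had medians of -0.19, 0.20 and 0.12 against the scrambled line alone. In the immediate early list, 3 genes were higher and 4 lower adjusted over the list alone. Markers of hepatocytes, macrophages and leukocytes, endothelium, biliary epithelium, and portal fibroblasts, mesothelium and smooth muscle also had 0 of 16, 18, 14, 10 and 20 members past the threshold. Their camera adjusted p were 0.629 for the first 4 and 0.926 for the last, in which 1 gene was higher and 1 lower adjusted over the list alone. Of the 21 lists, 3 were called by camera and 0 with an estimated correlation, and by fry 0 moved one way on balance. Camera called 2 with quantile normalisation, 2 with the probe set of largest variance per gene, and 2 with line as a random block and the passage number as a replicate block.

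In all, limma on the 5 line means called 247 probe sets, 166 higher and 81 lower, of which 236 had all 6 clone arrays apart from the 4 control arrays. Over all tested probe sets 2064 were apart in this way, a share of 7.50%. In the other 9 splits of the 5 lines into 3 and 2 the share was 0.650% to 2.29%, and with the lines as exchangeable units chance gives up to 20%. The count fell to 0 without clone S1, 2 without S4 and 0 without S5, and it was 3 without passage 43 and 80 without passage 42. It was 1315 with line as a random block over the 10 arrays and 1205 with the passage number as a replicate block added. The estimated correlation between passages of a line was 0.0486 in the first of these fits and 0.210 in the other. Both thus treated the passages of a line as largely separate replicates.

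Each clone was then set against the control lines, with p-values that measure only the spread between passages of a line. In clone S1, Plagl1 rose by 6.30 (SE 0.26), Timp3 by 4.50 (SE 0.19), Cxcl12, a chemokine of stromal cells, by 4.19 (SE 0.44) and Pdpn, the mucin-like podoplanin, by 4.10 (SE 0.15). Thy1 was at -5.54 (SE 0.18), Fgf9, a secreted fibroblast growth factor, at -4.12 (SE 0.71) with a mean of 4.42 in S1, near the floor, and Mmp2 at -4.65 (SE 0.45). In clone S4, Plagl1 rose by 6.64 (SE 0.26), Fam13a by 4.53 (SE 0.26) and Pdpn by 3.99 (SE 0.15), while Col15a1 fell by 6.24 (SE 0.26). In clone S5, Cxcl12 rose by 3.79 (SE 0.44) and Pappa2 by 4.21 (SE 0.39), while Srgn, the granule proteoglycan serglycin, fell by 3.57 (SE 0.43). The lowest values also included Aspn, a small leucine-rich proteoglycan, at least 11.1-fold lower in S4, and Eif2s3y, a translation initiation factor gene of the Y chromosome, at least 70.4-fold lower in S5 (SE 0.15, limma adjusted p = 6.26e-06). These are lower bounds, because Aspn was at the floor on all 6 clone arrays and Eif2s3y on both S5 arrays. For Col15a1 the single-clone values come from another probe set than the -4.40 given for the clones together.

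Limma called 1058 probe sets in clone S1 (578 higher, 480 lower), 860 in S4 (514 and 346) and 818 in S5 (445 and 373). With the passage number as a replicate block the counts were 1897, 1525 and 1566. Without the clone's own array of passage 42 or 43 they were 333 and 147 for S1, 214 and 225 for S4, and 176 and 132 for S5. Without the scrambled array of passage 43 they were 623, 577 and 458, and without the untransfected array of passage 43 they were 736, 661 and 541. The same way in all 3 clones were 553 probe sets, 315 higher and 238 lower, and 977 with the replicate block. Without 1 clone array they were 113 to 238, and without the scrambled or the untransfected array of passage 43 they were 320 and 383. Independent lists of these sizes would share 0.175 higher and 0.0820 lower probe sets, and 20 simulations of unchanged clones against the same controls shared 0. The simulations held the spread between passages only and no differences between lines, so they do not show what unchanged clones with ordinary differences between lines would share, and part of the overlap may come from the shared controls. Fold changes of pairs of clones against both control lines correlated at 0.844 to 0.928 across probe sets, against 0.330 to 0.335 in the simulations. Their covariance was 0.115 to 0.133, against 0.00884 to 0.00899 in the simulations, which have the same limit. Where 1 clone was set against the scrambled and the other against the untransfected line, the correlation was 0.321 to 0.403. That arrangement shares no control array and was not simulated, so the simulated values are no reference for it. With the controls split in this way, 253 to 299 probe sets were called the same way in a pair of clones.

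Among the fixed lists, Bmp4 was higher in each clone, by 2.77, 2.62 and 2.75 in S1, S4 and S5, and TGF-beta and BMP signalling was higher by camera (adjusted p = 0.00798, 0.00127 and 0.0170). With an estimated correlation its adjusted p = 0.451, 0.360 and 0.729. Of its 40 genes, 2 rose and 1 fell in S1, 4 and 1 in S4, and 3 and 1 in S5, with 8 and 4, 11 and 4, and 7 and 4 adjusted over the list alone. For cholesterol synthesis and uptake, with 0 members past the threshold in any clone, camera gave adjusted p = 0.00141, 0.000316 and 0.00158, and adjusted p = 0.837, 0.739 and 0.858 with an estimated correlation. Of the contractile list, 3 genes rose and 2 fell in S1, 5 and 2 in S4, and 3 and 2 in S5 (8 and 6, 9 and 4, and 7 and 3 adjusted over the list alone), with Thy1 at -3.46 in S4 and -3.79 in S5. Acta2, the smooth muscle actin of activated stellate cells, was at 0.71, 0.98 and 0.65 against both control lines together, and at -0.74, -0.46 and -0.79 against the untransfected line alone. Egfr, the epidermal growth factor receptor and a reported target of miR-146a, was at -2.58, -1.99 and -1.97, past the threshold in each clone. Egfr also fell in the scrambled against the untransfected line, as given below. Its falls against both control lines together are thus larger than those against the scrambled line alone. Irak1, Traf6 and Smad4 did not pass in any clone, and the lowest limma adjusted p among them was 0.0825, for Traf6 in S5. For the list of reported targets, fry gave a downward movement with adjusted p = 0.0731, 0.0424 and 0.0383 in S1, S4 and S5, and camera, against other genes, gave adjusted p = 0.916, 0.545 and 0.598. Fry called no other of the 21 lists in a single clone. Of the hepatocyte markers 0, 1 and 1 of 16 rose in S1, S4 and S5 and none fell (0, 2 and 1 higher adjusted over the list alone). Of the biliary markers 0, 1 and 0 of 10 rose and none fell, with the same counts adjusted over the list alone. Of the portal fibroblast, mesothelial and smooth muscle markers 1, 2 and 2 of 20 rose and none fell, with 3, 4 and 3 higher and 1, 2 and 2 lower adjusted over the list alone, and the list's medians were -0.0050, -0.05 and -0.10. Of the macrophage and leukocyte markers 1 of 18 fell in S4, with 3 lower adjusted over the list alone.

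The 3 clones were compared with each other by an F test. Eif2s3y had the widest range of clone means, at 6.11 on the log2 scale (limma adjusted p = 2.43e-05), a lower bound. Its intensity was 20 on both S5 arrays and between 1106 and 1681 on the other 8. Igf2bp3, an RNA-binding protein of fetal tissue, had log2 means of 7.76 in S1, 4.89 in S4 and 5.36 in S5, a range of 2.87 (limma adjusted p = 0.00670). One probe set of Abo3, a glycosyltransferase of the ABO family, was at the floor in S1 and both control lines and at 5.89 in S4 and 7.01 in S5, while the other was at 4.68 in S1, 4.37 in the scrambled line and 6.54 in S5. Elavl2, a neuronal RNA-binding protein, was above the floor in S4 alone, at 5.93. In all 9 probe sets differed, and 749 did so at an unadjusted p under 0.05. The count was 25 with the passage number as a replicate block, 17 with a trended and robust prior, 2 with 1 probe set per gene and 4 without the untransfected arrays.

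The scrambled line was set against the untransfected line to measure how far 2 lines without the microRNA differed. Postn, the matrix protein periostin, fell by 7.88 (SE 0.47), from a mean log2 level of 12.95 in the untransfected line to 5.06 in the scrambled line. Lower levels were also found for Actg2, a smooth muscle actin, at -4.97 (SE 0.58), Lpl, lipoprotein lipase, at -4.38 (SE 0.35), Gzmb, the protease granzyme B, at -4.34 (SE 0.96), Cdh11, a cadherin of mesenchymal cells, at -4.23 (SE 0.40), and Hey2, a Notch target, at -4.13 (SE 0.44). Lmcd1 was at -4.16 (SE 0.22) and Arhgap44 at -3.95 (SE 0.12). Vnn1, a pantetheinase, rose by 4.38 (SE 0.24), Ackr3, a decoy chemokine receptor, by 3.99 (SE 0.57), Sema3d, a secreted semaphorin, by 3.93 (SE 0.44), Vcam1, an adhesion molecule for leukocytes, by 3.86 (SE 0.67), and Mycn, a Myc family transcription factor, by 3.77 (SE 0.30). Ntm rose by 4.34 (SE 0.48), Nxf7 by 4.08 (SE 0.43) from an untransfected mean of 4.48, near the floor, and Psca by 3.67 (SE 0.17).

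Of the 27 contractile and activation genes, 17 fell and none rose, with 19 lower and 2 higher adjusted over the list alone. Cnn1, the smooth muscle calponin, was at -3.79, Acta2 at -2.89 and Myl9, a myosin light chain, at -2.41, and the list was lower by camera (adjusted p = 5.54e-12), with adjusted p = 0.0150 with an estimated correlation. Of 51 matrix genes, 4 rose and 9 fell, with 4 and 20 adjusted over the list alone. Col4a1, a chain of basement membrane collagen, was at -3.47, while the laminin chain Lama2 was at 2.93 and Col14a1 at 2.86. Camera placed the list lower (adjusted p = 2.57e-05, with adjusted p = 0.322 with an estimated correlation). Of 40 TGF-beta and BMP genes, 2 rose and 8 fell, with 2 and 10 adjusted over the list alone. Nbl1 and Inhbb were at 2.78 and 2.63, Tgfb3 and Grem1 at -2.52 and -2.40, and camera placed the list lower (adjusted p = 0.00995, with adjusted p = 0.322 with an estimated correlation).

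Of 27 cholesterol genes, 4 rose and none fell, with 9 higher adjusted over the list alone. They were Tm7sf2 at 1.09, Ebp at 1.04, Mvd at 1.04 and Mvk at 0.97, all enzymes of sterol synthesis, and camera gave adjusted p = 2.73e-08, with adjusted p = 0.572 with an estimated correlation. The cell cycle list had a median of 0.69 and was higher by camera (adjusted p = 5.49e-06, with adjusted p = 0.726 with an estimated correlation), while the 1 of 52 members past the threshold, the cyclin Ccnd2, was at -1.05. Of 34 interferon response genes, Cxcl10, an interferon-induced chemokine, rose by 2.02 and Oasl by 1.26, with 6 higher and 5 lower adjusted over the list alone and camera adjusted p = 0.00995, with adjusted p = 0.748 with an estimated correlation. Among the 23 reported targets of miR-146a, Egfr fell by 3.09, Notch1 fell by 1.49 and Tlr4 rose by 1.39, and camera gave adjusted p = 0.553 for the list and fry a downward movement with adjusted p = 0.00510. The portal fibroblast, mesothelial and smooth muscle markers had 4 higher and 2 lower, among them Mcam at -2.24, Upk1b at 1.91 and Msln at 1.67, and camera adjusted p = 0.981. Of the 18 macrophage and leukocyte markers, Csf1r, the receptor of a macrophage growth factor, rose by 0.78.

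In all, 1679 probe sets differed between the scrambled and the untransfected line by limma, 614 higher and 1065 lower. The count was 3602 with the passage number as a replicate block, 3224 and 611 without the untransfected array of passage 42 or 43, and 608 and 901 without the scrambled array of passage 42 or 43. The untransfected arrays also stood apart in their controls. The poly-A spike-ins, added before labelling, averaged 10.37 on the log2 scale on the 2 untransfected arrays and 8.61 on the other 8, the 5S ribosomal RNA probe set 9.27 against 6.96, and the hybridisation spike-ins, added after labelling, 11.29 against 11.26. The 3' minus 5' difference of actin was 0.87 against 0.57.

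Runs of neighbouring genes were also examined, as medians over windows of 25 genes in chromosome order. Between the scrambled and the untransfected line, 68 of 76 genes from Ptges3l to Srp68 were higher, with a median of 0.38, and 140 of 155 genes from Pcolce to Chfr, with a median of 0.40. The most extreme window had a median of 0.56, where 5% of 1000 permutations of the gene order exceeded 0.37 (permutation p = 0.000999, the smallest they can give). Between the clones and the untransfected line, the same runs had medians of -0.10 and -0.05, the most extreme window was 0.23 and the permutation bound 0.29 (permutation p = 0.717). Between the clones and both control lines together, 5 runs passed the bound of 0.22. One of them, the 25 genes from Sf3b5 to Slc18b1 with Plagl1 among them, was higher in the clones against each control line, with medians of 0.11 against the scrambled and 0.15 against the untransfected line, and its median was 0.07 between the scrambled and the untransfected line. Against either control line alone its window stayed within the bound. Of 68 genes in the order that differed between the clones and both control lines, 8 (11.8%) lay in windows shifted in that comparison, which held 4.97% of all genes in the order, and 60 lay outside.

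**Figure D3:**
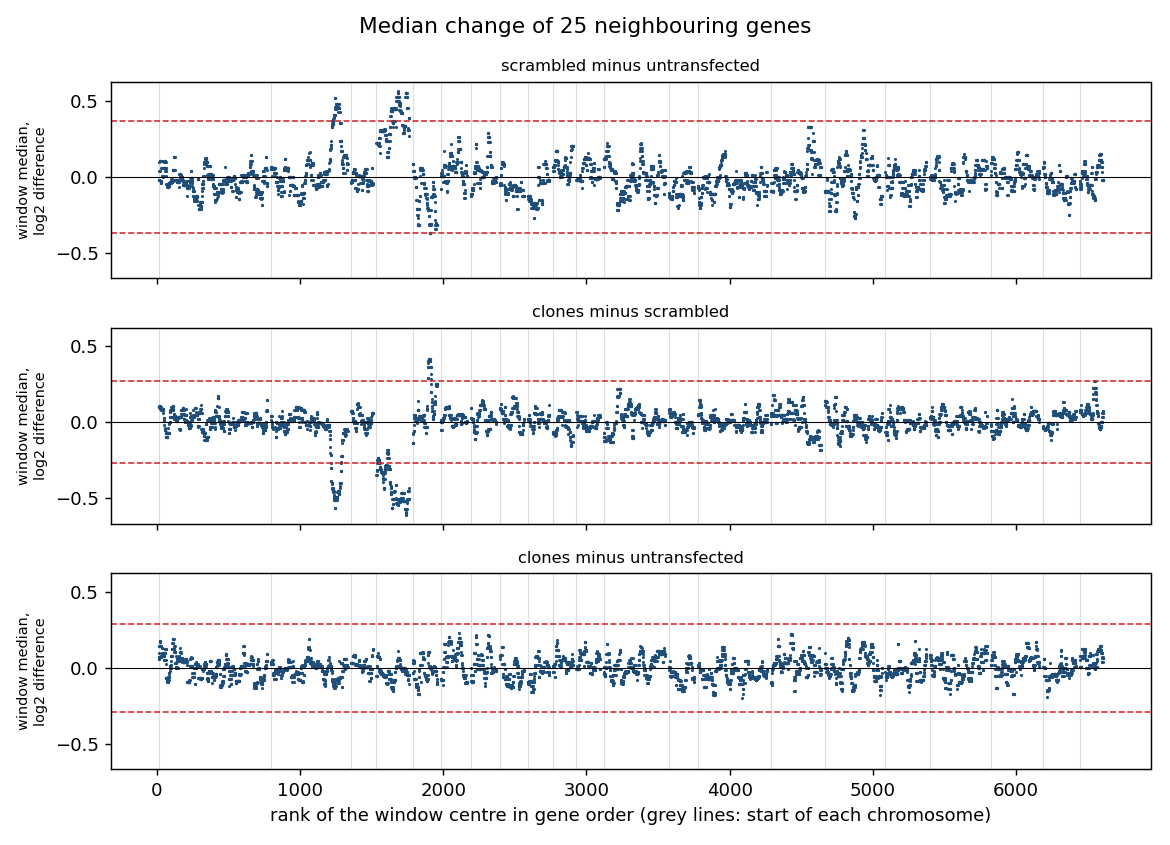
Median log2 difference over 25 neighbouring genes (vertical axis) against the rank of the window in gene order (horizontal axis), for the scrambled minus the untransfected line, the clones minus the scrambled line and the clones minus the untransfected line. Each point is a window, grey lines mark the start of each chromosome, and dashed lines are the bounds that 5% of permutations exceeded; 2 runs of genes pass them in the comparisons with the scrambled line, up to 0.56 and down to -0.61, 2 others pass in the clones minus the scrambled line, from Kifap3 to Parp1 up to 0.42 and from Nap1l3 to Klhl13 up to 0.27, and no window does between the clones and the untransfected line.

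The change from passage 42 to passage 43 was tested within the 5 lines. Over probe sets, this change correlated at 0.541 to 0.648 between clones and at 0.136 between the control lines, so the clones weigh most in what follows. Dcn rose by 2.04 (SE 0.27) and Lum, the related proteoglycan lumican, by 1.58 (SE 0.21). Pln, a regulator of the calcium pump of muscle, rose by 1.84 (SE 0.18), Fibin by 1.58 (SE 0.29), Tmem178a by 1.57 (SE 0.18), Egr2, an early response transcription factor, by 1.38 (SE 0.24) and Igfbp5, an insulin-like growth factor binding protein, by 2.29 (SE 0.41). Lower values were found for Rassf4 at -1.71 (SE 0.12), Il1rl1 at -1.58 (SE 0.21), Orc1, a subunit of the replication origin complex, at -1.18 (SE 0.13), Tnc, the matrix protein tenascin C, at -1.16 (SE 0.13), and Tfrc, the transferrin receptor, at -1.16 (SE 0.18). Prl8a9 fell by 1.89 (SE 0.40), with 4 of the 6 clone arrays at the floor.

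Of 52 cell cycle genes, 35 fell and none rose, and 50 were lower adjusted over the list alone. Ccna2 was at -1.01, Ccnb1 at -0.89, Kif23 at -0.85 and Bub1b at -0.84, all genes of mitosis, and camera gave adjusted p = 4.79e-28, with adjusted p = 0.538 with an estimated correlation. Of 34 matrix proteases and inhibitors, 8 rose and none fell, with 14 higher and 3 lower adjusted over the list alone. Serpine2 was at 1.16, Mmp2 at 0.87, Mmp11 at 0.71 and Ctsd at 0.66, and camera gave adjusted p = 3.58e-05, with adjusted p = 0.123 with an estimated correlation. Camera also placed higher the interferon response (2 of 34 rose, Ifitm3 at 0.66 and Gbp2 at 0.55, adjusted p = 0.000279) and inflammatory genes (3 of 37 rose, Vcam1 at 1.06, Cxcl16 at 0.58 and Icam1 at 0.54, adjusted p = 0.0158), with adjusted p = 0.637 and 0.538 with an estimated correlation. It placed lower cholesterol synthesis (1 of 27 fell, Scd at -0.73, adjusted p = 0.000410) and endoplasmic reticulum and amino acid stress (8 of 36 fell, among them Psph at -0.84 and Slc7a11 at -0.74, adjusted p = 0.00357), with adjusted p = 0.637 for both with an estimated correlation. Counts adjusted over the list alone were 2 higher for interferon, 3 higher for inflammatory, 1 lower for cholesterol and 9 lower for stress genes. With an estimated correlation, 0 of the 6 lists called here and 1 of the 6 called between the scrambled and untransfected lines, the contractile list, passed. Without the 2 untransfected arrays 3 of the 6 passage lists were called by camera with the preset correlation, and the inflammatory, cholesterol and stress lists no longer passed, each at adjusted p = 0.0621.

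In all, 1520 probe sets differed between the passages by limma, 670 higher and 850 lower, of which 47 changed at least 2-fold. The count was 0 without S1, without S4 or without S5, 782 without the scrambled line, 1698 without the untransfected line and 156 without line as a block. The change between passages differed between clones and control lines at 5 probe sets. Anxa3 changed by 0.20 in the clones and -1.91 in the control lines, a difference of 2.11 (SE 0.11, limma adjusted p = 0.0114). Gzmb, at 2 probe sets, differed by -2.27 and -2.49 (limma adjusted p = 0.0114 and 0.0249), Vgf, a secreted neuropeptide precursor, by 1.83 (limma adjusted p = 0.0270) and Nr4a1, an early response nuclear receptor, by 1.60 (limma adjusted p = 0.0403).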

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

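The tests of the untransfected array batch, of segments gained in the scrambled line, of the run with Plagl1, of cell type markers in single clones, of other splits, of the poly-A spike-ins and of the difference in passage change were chosen only after the results were seen.

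The 3 clones stood together apart from both control lines. Each clone differed from the scrambled line at 948 or more probe sets and from another clone at 9 or fewer. The differences from the scrambled line hold no untransfected array, so an array batch of the untransfected line could not have made them, whatever the counts. They therefore cannot weigh such a batch. Whether such a batch fed the calls against both control lines together was not tested. In the clones together 0% of the members of any of 5 lists of other cell types rose past the threshold, under the 10% written beforehand, but that test called only 166 probe sets upwards. In the clones together or in a single clone, at most 6.25% of the hepatocyte, macrophage and endothelial markers rose, under that bound. Adjusted over the list alone, 0 macrophage and endothelial markers were higher, which argues against those cells. By that measure 2 of 16 hepatocyte markers were higher in S4 and 1 in S5. Alb, chosen after its values were seen, changed by -0.06 to 0.12 in single clones, so hepatocytes are argued against by Alb and the bound but not by that measure. Up to 10% of the biliary markers in S4, and of the portal fibroblast, mesothelial and smooth muscle markers in S4 and S5, rose, which is not under that bound, while 2 portal fibroblast, mesothelial and smooth muscle markers were lower in each of these clones adjusted over the list alone, so those cells stay open. Shared gain or loss of segments in the clones met its written prediction, with an extreme window median of 0.336 against a permutation bound of 0.221, but the clones against the untransfected line reached only 0.228 against 0.291, so that prediction did not separate the clones from the scrambled line, where 0.563 against 0.368 is consistent with segments gained in that line. The runs from Kifap3 to Parp1 and from Nap1l3 to Klhl13 were lower in the scrambled line than in the clones, and had medians of -0.24 and -0.17 in it against the untransfected line, which a gain would not give. The run from Sf3b5 to Slc18b1, which holds Plagl1, was higher in the clones by 0.110 and 0.153 against the scrambled and untransfected lines, and its window of 0.222 passed the bound of 0.221 for both together but neither bound alone, so a gain of that run in the clones stays open. The reported targets as a list met the condition written beforehand for no effect, with a median of -0.0373 within the middle of random lists (percentile 33.0). Members went both ways, 16 below 0 and 7 above, and a list median cannot exclude a fall of some targets, so that stays open. This limit was added after the values were seen. By fry the list moved downward in S4 and S5 (adjusted p = 0.0424 and 0.0383), but also in the scrambled against the untransfected line (adjusted p = 0.00510). Only 10 splits of the 5 lines exist, too few for a share under 0.05, and 1 of them, the real one, called as many as 247 probe sets, with 0 in the highest other, while an effect of miR-146a and a shared clonal origin of S1, S4 and S5 were not told apart by any test here.

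The poly-A spike-ins were higher on the untransfected arrays by 1.76 on the log2 scale and the 5S ribosomal RNA probe set by 2.31, signals outside the main measurement. Hybridisation spike-ins, added after labelling, differed by 0.0315, which is consistent with less sample RNA or a separate labelling of those 2 arrays. Both untransfected arrays carry it, and no biological explanation was tested.

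Passage 43 differed from passage 42 at 1520 probe sets, and at 0 without S1, S4 or S5. Only 16 splits part all 5 pairs of passages, too few for a share under 0.05, and 1 of them, the real one, called as many, with 0 in the highest other. Of 100 splits drawn from all 126, most of which part only 1 or 3 pairs, the highest other called 29. The hybridisation spike-ins rose in 5 of 5 lines, by 0.04 to 0.20, and the poly-A spike-ins in 3, which is consistent with a difference in hybridisation between the passages. That explanation stays open beside an effect of the passage itself, which was not tested apart from it.

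Differences between the clones by the F test marked 9 probe sets. The range of clone means was 6.11 for Eif2s3y, 2.87 for Igf2bp3, 2.69 and 1.86 for the probe sets of Abo3, and 1.61 and 1.51 for those of Elavl2. Those of Eif2s3y, of the first Abo3 probe set and of Elavl2 are lower bounds, because at least 1 clone was at the floor. Ranges of 3 unnamed probe sets were 2.88, 2.06 and 2.25. Passage changes in clones minus those in control lines were 2.11 for Anxa3, 1.83 for Vgf, 1.60 for Nr4a1, and -2.27 and -2.49 for the probe sets of Gzmb.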

How the results depend on the processing

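Runs without the untransfected arrays (differences between clones, passage and its lists) and the estimated correlation for the scrambled and passage lists were chosen after seeing the data. The clones against control lines gave 247 probe sets, and 207 to 276 under quantile normalisation, median centring, a dim filter or a trended robust prior. They gave 1693 with the scrambled and 2968 with the untransfected line alone, 1315 with line as a random block, 1205 with that and the replicate block, and 2200 with the spread between passages. Leaving out a line gave 0 to 2968, and without passage 42 or 43 there were 80 or 3. A 2-fold minimum gave 147 for the clones, 549, 450 and 450 for S1, S4 and S5, 739 for the scrambled line, 303 for calls shared by the clones and 47 for passage. With 1 probe set per gene, where fewer were tested, the counts were 141, 622, 513, 492, 838 and 327, and 2 for differences between clones. The replicate block gave 1897, 1525 and 1566 for the single clones, 3602 for the scrambled line, 977 for shared calls and 25 for differences between clones. Of the genes named for the clones together, 17 newly passed with line as a random block, and 21 newly passed and 2 no longer passed with the replicate block added to it. Leaving out 1 array gave 147 to 1320 for S1, 214 to 1114 for S4, 132 to 1018 for S5, 608 to 3224 for the scrambled line, 113 to 699 for shared calls and 4 to 8 for differences between clones. Where an arm kept 1 array, it was assumed to vary like the others. Differences between clones were 17 with a trended robust prior and 4 without the untransfected arrays. Passage gave 156 with no line block, 0 to 1698 without a line and 782 without the scrambled line.

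Of 21 lists, 3 were called for the clones, 0 with an estimated correlation, 0 by fry and 7 with the scrambled line alone, and leaving out a line gave 2 to 7. Quantile normalisation, the probe set of largest variance per gene, and the replicate block with line as a random block each gave 2 for the clones. With an estimated correlation 1 was called for the scrambled line and 0 for passage. With the preset correlation 3 were called for passage without the untransfected arrays. Without the scrambled line, TGF-beta and BMP signalling and endoplasmic reticulum stress no longer passed for the clones. The median of the cholesterol list turned to -0.0060 with the scrambled line alone. Leaving out a line gave -0.0060 to 0.76 for it, -0.26 to 0.36 for the contractile and -0.44 to 0.26 for the cell cycle list, which both turned without the scrambled line. With the scrambled line as only control, Egln3 turned to 0.072 in S4 and 0 in S5. With the untransfected line as only control, Acta2 turned to -0.74, -0.46 and -0.79 in S1, S4 and S5, Vldlr to -0.16 in S1, and Cxcl10 to 0.13, Tagln to -0.12 and Postn to -1.56 in S4. The cause was not tested. Over all alternatives, 1473 values of single genes kept their side of the threshold for the clones together, 155 newly passed and 164 no longer passed. The same 3 counts were 1206, 37 and 87 for S1, 1173, 41 and 123 for S4, 1163, 35 and 132 for S5, 828, 27 and 117 for the scrambled line, and 818, 35 and 267 for passage. A value that changed direction without passing in either fit was counted as kept. For the clones together, a control line alone and leaving out the other are the same fit, counted under both names. So was the passage fit without the untransfected line. The seed-site test and its 6 alternatives were not run. Signal over background was limited by the floor of 20.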

Other observations

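Neither part of what follows was planned; both were chosen after the values were seen. Of 2509 probe sets above 1000 intensity units on the 8 other arrays, 1 was at the floor on both S5 arrays, that of Eif2s3y. The same count was 0 for the untransfected line, the scrambled line, S1 and S4, over 2710, 2665, 2526 and 2519 probe sets. A probe set of Uty, another gene of the Y chromosome, was at 258 and 256 in S5 and between 230.3 and 313.5 on the other arrays. The other Uty probe set was between 20.6 and 28.6 on all arrays, and Sry between 20 and 23.4. Both are near the floor, so they do not tell the lines apart.

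Other genes of the fixed lists passed in single clones. Ccl7, a monocyte chemoattractant, was at -1.44 in S4 (limma adjusted p = 0.0350) and -1.60 in S5 (limma adjusted p = 0.0240). Of the 37 inflammatory and NF-kB response genes, 1 rose in each clone, and 0, 1 and 2 fell in S1, S4 and S5. Adjusted over that list alone, 1, 2 and 1 were higher and 0, 3 and 2 lower. Fgf1, a fibroblast growth factor, was at 1.98, 2.17 and 1.78 in S1, S4 and S5, and Gas6, a ligand of TAM receptors, at 1.58, 2.07 and 1.66, all past the threshold. Of the 38 growth factor genes 2, 4 and 2 rose and 3, 3 and 1 fell in S1, S4 and S5, with 3, 4 and 2 higher and 4, 6 and 4 lower adjusted over the list alone. Those that fell were Areg, Igf1 and Pdgfra at -0.44, -0.57 and -1.79 in S1, Fgfr1, Flt1 and Kitlg at -0.80, -1.08 and -1.11 in S4, and Flt1 at -0.86 in S5. Ccnd2, a cyclin of the G1 phase, was at -1.53, -2.80 and -1.20 in the same clones.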
